A study of Mus musculus with 8 samples.

How the data were processed

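RNA from a mouse epicardial cell line was sequenced on an Illumina instrument in 8 libraries, 4 with an empty lentiviral vector (EV) and 4 with CRISPR/Cas9 directed at Hdac3 (KO), per the labels. The series design text and the labels' protocols describe Trizol extraction of total RNA and libraries made by a sequencing company. The authors deposited raw counts per gene, whole numbers for 35275 genes, and a table of FPKM values for the same genes with coordinates. The submitters' processing notes name the build mm10 and DESeq 1.6.3, while the series design text names DESeq2 and an adjusted p of 0.05. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Without a strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads of ribosomal protein genes and other families may be shared with pseudogenes. The deposited FPKM values equal the counts divided by gene length and by the sum of the library's column for 100% of nonzero values, within 1e-06, and like the raw counts they carry no correction for library composition.

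Libraries were grouped by title. The characteristics of KO replicate 1 name the empty vector while its title says KO, and the results were recomputed without it. Within each group, pairs of replicates differed by more than counting noise (chi-square per degree of freedom from 4.01 to 13.2 over genes with at least 20 counts), so none was counted as a duplicate. Library totals ranged from 18063745 to 24564892 counts. A count of 3 corresponded to between 0.122 and 0.166 CPM, which sets the level below which a transcript cannot be told from absence at this depth.

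The main test was edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total 15), the quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. Of the genes, 12801 passed the filter. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-normalized CPM, given as mean ± SD over 4 libraries. The biological coefficient of variation was 6.41%. On counts simulated from these libraries for 12801 genes, the test recovered 44, 74, 96 and 100% of genes changed by 1.25, 1.5, 2 and 4-fold and called 9 of 12601 unchanged genes. Only 50 genes were changed at each fold and genes were drawn independently, while 26.0% of the tested genes passed in the real data. These rates therefore need not hold for the real libraries. Single genes fixed in advance also had an exact permutation test over all 70 arrangements, two-sided.

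Before the data were examined, 45 gene lists, the test and the rule for naming genes were fixed. The rule took Hdac3, Fgf9 and Igf2, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and groups that did not overlap, leaving out gene models without a proper name, and then, from each list, up to 4 members with the smallest adjusted p where the list passed or at least 1 in 3 tested members did, and otherwise at most 2. A few genes that this rule takes are not reported here. Lists with at least 5 tested genes, 42 of the 45, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset correlation of 0.01, adjusted over lists. Camera asks whether a list moved more than other genes. It called 11 lists, 4 up and 7 down. With a correlation estimated from the data, 5 calls held: mitosis, DNA replication, FGF receptor response, Wnt targets and modulators, and the microRNA targets. The test called 1 of 44 random lists on simulated counts. Genes were simulated independently there, while the estimated correlation within the real lists reached 0.655 (cytosolic ribosomal proteins). That simulation therefore does not show how often lists whose members vary together are called by chance. Some lists share genes. Among named genes, Slit2, Irf9, Lats2, Rian and mt-Nd4 overlap another gene on the same strand, and beside those given with the results, Ncor1, Hdac7, Ncam1, Psmb10, Icam1, Bhlhe40, Thra, Nr2f2, Ddit3, Dnaja1, Hspe1, Hk2, Me1, mt-Nd6, Rps18, Rpl5, Mest, Dgcr8 and Ago2 overlap one on the opposite strand.

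Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, library totals alone, other filters, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a filter (FPKM of at least 0.5 in 4 libraries), the replicate number as a block, each library left out in turn, and fry in place of camera. Chosen after the data were examined were the fits without KO replicates 2 and 3 and the list tests without Fgf9 and Igf2. For 3' UTR sequences and hairpin positions, GENCODE M21, of the same build but another release than the table, was used, and 98.2% of the tested protein-coding genes had a 3' UTR there. MicroRNA libraries were not analysed here.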

Results

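Messenger RNA levels were measured by RNA sequencing in a mouse epicardial cell line. The epicardium is the cell layer that covers the heart and secretes growth factors to the muscle below it. Of the 8 libraries, 4 came from cells given an empty lentiviral vector (EV) and 4 from cells in which CRISPR/Cas9 was directed at Hdac3, the histone deacetylase of the NCoR corepressor complex (KO). The deposited counts summed to 18063745, 22289125, 21375393 and 20646970 in EV replicates 1 to 4 and to 19173812, 20701054, 23688247 and 24564892 in KO replicates 1 to 4, and between 16431 and 16761 genes had at least 1 count in a library. The characteristics of KO replicate 1 name the empty vector although its title says KO, so libraries were grouped by title. On the first principal component, which held 48.8% of the variance, the EV libraries lay between −22.3 and −16.9 and the KO libraries between 16.3 and 20.1, with KO replicate 1 at 20.1. Nothing in the labels says that the replicates were separate cultures, so p-values judge a group difference only against the spread between these libraries. Any other difference between the EV and KO cells than the one aimed at Hdac3 would be part of that group difference.

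Hdac3 (ENSMUSG00000024454, mm10 chromosome 18, 37935844 to 37954988) showed no detectable difference in transcript level between the groups. It stood at 60.3, 61.4, 64.0 and 61.7 CPM (counts scaled to a common library total) in EV replicates 1 to 4 and at 63.2, 56.9, 63.9 and 62.6 CPM in KO replicates 1 to 4. The means were 61.9 ± 1.53 (SD, n = 4) and 61.6 ± 3.23 CPM (SD, n = 4), with a log2 fold change of −0.005 (SE 0.0528, edgeR adjusted p = 0.956). The difference of the means was smaller than the SD within either group, and an exact permutation test, two-sided, gave p = 0.943. Its sign turned when EV replicate 3 (0.01) or KO replicate 2 (0.03) was left out. An edit by Cas9 can disrupt a protein without lowering its transcript, so the Hdac3 level in these counts does not check the group labels.

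**Figure D1:**
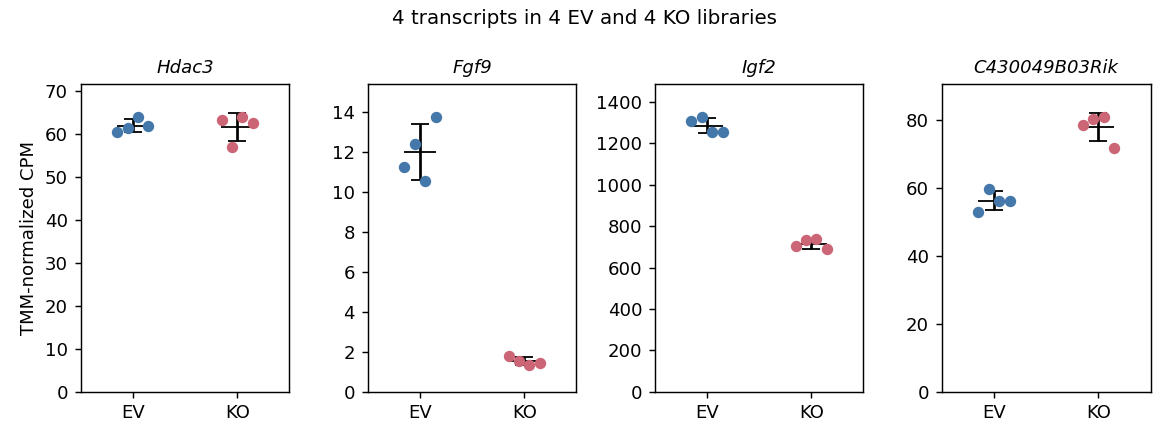
TMM-normalized CPM (vertical axes, from 0) of Hdac3, Fgf9, Igf2 and the noncoding transcript C430049B03Rik in 4 EV and 4 KO libraries; each point is a library, the horizontal line the mean and the bar 1 SD to each side. Hdac3 overlaps between the groups, Fgf9 lies between 1.34 and 1.80 CPM in KO and between 10.6 and 13.8 CPM in EV, and Igf2 lies near 716 CPM in KO and 1287 CPM in EV.

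The single comparison of the series, KO against EV, asked which transcripts differ between empty-vector cells and cells with CRISPR/Cas9 directed at Hdac3. The series title places the question in a microRNA pathway that bears on growth of the heart muscle. Fgf9 and Igf2 fell in KO, as did all 26 tested genes of mitosis, 7 of 13 Wnt targets and modulators and 9 of 13 genes that respond to FGF receptors. The metalloproteinase genes Mmp3 and Mmp13, the keratin genes Krt13 and Krt8 and the serpin genes Serpina3n, Serpinb9b and Serpinb1a rose. Of 12801 genes tested, 3324 (26.0%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1613 higher and 1711 lower in KO. Most differences were small: the median absolute log2 fold change of these genes was 0.31, and 85 were at least 2-fold higher and 190 at least 2-fold lower. The balance of directions depended on the scaling. With library totals alone 1039 genes were higher and 2414 lower, and in the authors' FPKM values 896 were higher and 2076 lower with a pseudocount of 1 (897 and 2068 with 0.1, and 766 and 1809 without a filter). Without KO replicates 2 and 3, a choice made after the data were examined because these libraries held the most counts of liver genes, 1974 genes passed. Fewer libraries can lower such counts by themselves, and no other pair was left out for comparison. Smaller counts without KO replicates 2 and 3, here and below, therefore do not show that these libraries carried a difference.

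Fgf9, a secreted fibroblast growth factor that acts on heart muscle, had the largest fall of the genes named by rule. Fgf9 (ENSMUSG00000021974, chromosome 14, 58070547 to 58112337) went from 12.0 ± 1.41 to 1.52 ± 0.205 CPM (SD, n = 4 each), a log2 fold change of −2.99 (SE 0.145, edgeR adjusted p = 2.37e-11), and was 7.94-fold lower. Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), an insulin-like growth factor, went from 1287 ± 38.2 to 716 ± 23.7 CPM (SD, n = 4 each), a log2 fold change of −0.85 (SE 0.0427, edgeR adjusted p = 4.65e-11). Both gave the smallest p that 4 against 4 libraries allow in a two-sided exact permutation test (p = 0.0286). Igf2 overlaps Igf2os on the opposite strand, and the strand setting of the counts is not given in the sources used here. The pair was named in advance because published work on epicardial Hdac3 centres on them, so their direction is not independent evidence if they were chosen there from these libraries.

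Among 34 secreted growth factors tested, 6 rose and 17 fell (7 and 18 adjusted over the list alone), with a median log2 fold change of −0.19. Wnt5a, a noncanonical Wnt ligand, fell to −0.60 (SE 0.0419), and the chemokine Cxcl12 rose by 0.52 on the log2 scale (SE 0.0465). The list passed limma's camera test against other genes (adjusted p = 0.0229), but not with an estimated correlation (adjusted p = 0.102), with library totals alone (adjusted p = 0.0732) or without EV replicate 1 (adjusted p = 0.0580). Without Fgf9 and Igf2, a choice made after the data were examined, its adjusted p was 0.146. Of 13 genes that respond to FGF receptors tested, 0 rose and 9 fell (0 and 10 adjusted over the list alone), with a median of −0.24. Among these were the feedback inhibitors Spry4 (−0.71, SE 0.0590), Spred1 (−0.44, SE 0.0445) and Dusp6 (−0.55, SE 0.0619) and the transcription factor Etv5 (−0.72, SE 0.0643). The camera test of this list gave an adjusted p of 2.02e-05 and, with an estimated correlation, an adjusted p of 0.0383. In the list of IGF binding and signalling genes, 12 were tested, 3 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.524). Igfbp4 (0.46), the mannose 6-phosphate receptor Igf2r (0.24) and Igf2bp3 (0.34) rose and Igfbp7 (−0.45) fell. Without EV replicate 4, 6 rose, and 3 fell without KO replicate 2, or 2 without EV replicate 1 or 4. Wnt5a, Igfbp7, Igf2r and Igf2bp3 overlap other genes on the opposite strand.

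The 10 largest rises included 2 keratin, 3 serpin and 2 matrix metalloproteinase genes. Krt13, a keratin of stratified epithelia, was 4.17-fold higher (5.11 ± 0.778 to 21.4 ± 2.67 CPM, SD, n = 4 each), and Krt8, a keratin of simple epithelia, had a log2 fold change of 1.66. The collagenase Mmp13 went from 41.1 ± 2.16 to 135 ± 7.35 CPM (log2 fold change 1.71, SE 0.0553, edgeR adjusted p = 9.55e-14) and the stromelysin Mmp3 from 17.0 ± 2.22 to 59.2 ± 4.44 CPM (1.79, SE 0.0822). The protease inhibitors Serpina3n (1.95), Serpinb9b (1.68) and Serpinb1a (1.54) rose too, as did the X-linked placental gene Plac1 (1.78, SE 0.0684). Alb, the albumin gene of liver (1.80, SE 0.277), and Ces1g, a carboxylesterase abundant in liver (1.51, SE 0.184), completed the 10. Alb held 68, 41, 56 and 49 counts in EV replicates 1 to 4 and 122, 266, 273 and 112 in KO replicates 1 to 4, and 40 of 44 detected liver genes had a higher mean in KO, with summed levels apart from Alb of 37.5 and 37.9 CPM in KO replicates 2 and 3 against 15.4 to 22.8 CPM in the other libraries.

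The 10 largest falls included 2 laminin chains of basement membrane and several cell-surface receptors. After Fgf9 came Nkd1, an intracellular Wnt antagonist (−2.66, SE 0.160), and Cd55, which protects cells from complement and went from 128 ± 12.5 to 23.9 ± 0.826 CPM (−2.42, SE 0.0673, edgeR adjusted p = 1.20e-14). Flt4, the receptor for Vegfc, fell to −2.41 (SE 0.131) and Cntfr, the receptor for ciliary neurotrophic factor, to −2.39 (SE 0.163). The laminins Lama4 (−2.20) and Lamc3 (−1.99), the transmembrane semaphorin Sema6a (−2.19), Ccdc64 (−2.06) and the imprinted gene Zdbf2 (−1.97) made up the rest. Cd55 and Lamc3 overlap antisense genes.

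**Figure D2:**
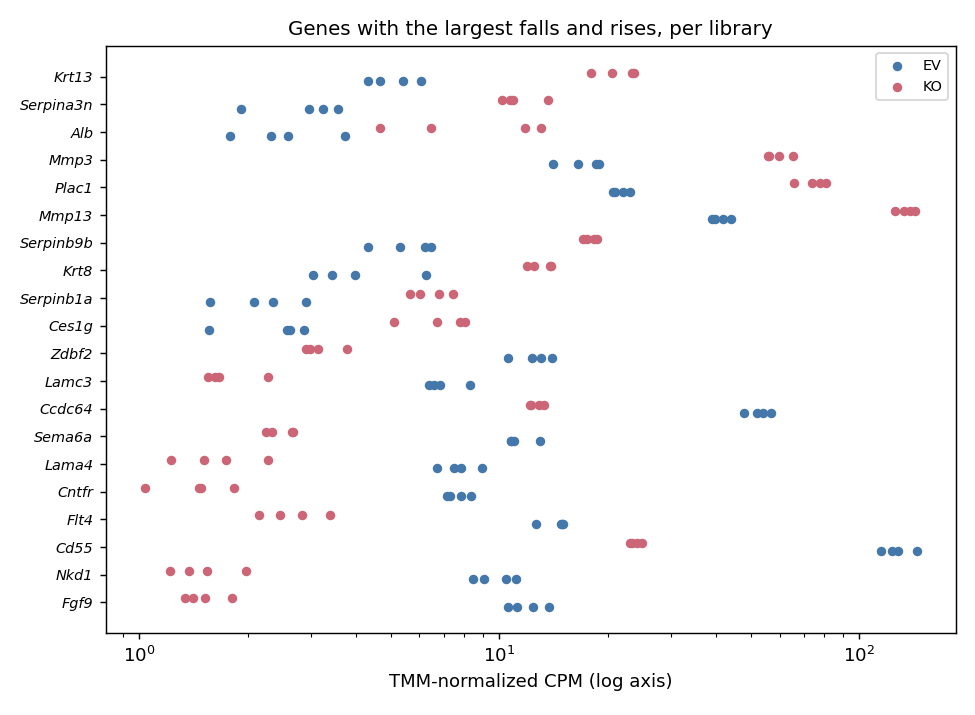
TMM-normalized CPM (horizontal log axis) of the 10 genes with the largest rises and the 10 with the largest falls, in 4 EV and 4 KO libraries; each point is a library. The groups are separate for all 20 genes, as the rule for naming them required, and Alb has the widest KO spread on this axis, from 4.66 to 13.0 CPM.

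All 26 tested genes of mitosis fell, over all genes and adjusted over the list alone, with a median log2 fold change of −0.70, among them the cyclin Ccnb2 (−0.79, SE 0.0636), the kinesin Kif23 (−0.87, SE 0.0682) and the spindle proteins Nusap1 (−0.94, SE 0.0757) and Tpx2 (−0.64, SE 0.0529). Camera gave this list an adjusted p of 6.81e-22 and, with an estimated correlation, an adjusted p of 0.0383. Of 28 genes of DNA replication tested, 1 rose and 15 fell (1 and 16 adjusted over the list alone), with a median of −0.18, among them the ribonucleotide reductase subunit Rrm2 (−0.48), Cdc45 (−0.53), Mcm10 (−0.41) and Mcm7 (−0.20). Their camera adjusted p was 6.63e-06 (adjusted p = 0.0383 with an estimated correlation), and 5 fell without KO replicates 2 and 3. Of 12 CDK inhibitors and D cyclins tested, 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.959). Cdkn1a, an inhibitor of cyclin-dependent kinases, and Ccnd1 rose by 0.72 and 1.07 on the log2 scale, while Ccnd2 (−0.61) and Ccnd3 (−0.28) fell. The median of that list was −0.039, its mean 0.056 and its test directed down, or up with library totals alone and without EV replicate 3, KO replicate 3 or KO replicate 4. Of 20 p53 targets, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.206), with Trp53inp1 at 0.31, Sesn1 at −0.44 and Plk2 at −0.25. The 5 rises became 3 without EV replicate 2 or 3, or KO replicate 2, 3 or 4, and with library totals alone. Nusap1, Cdc45, Mcm7, Ccnd1, Ccnd2 and Ccnd3 overlap genes on the opposite strand.

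Wnt targets and modulators were lower as a group. Of 13 tested, 1 rose and 7 fell, over all genes and adjusted over the list alone, with a median of −0.61. The median rests on which low counts are kept: it was −0.15 in DESeq2 (15 tested), −0.046 without a filter and −0.074 in FPKM without a filter (18 tested each), and −0.39, −0.40, −0.39, −0.39 and −0.34 without EV replicate 1, EV replicate 2, EV replicate 4, KO replicate 3 and KO replicate 4, with 7 falls in each. Beside Nkd1, the secreted inhibitor Sfrp1 went from 520 ± 17.4 to 248 ± 11.5 CPM (−1.07, SE 0.0460), the transcription factor Lef1 fell to −1.18 (SE 0.0829) and Apcdd1, a Wnt inhibitor at the cell surface, went from 37.5 ± 1.71 to 18.8 ± 1.38 CPM. The list therefore holds both targets and inhibitors of the pathway that fell. Its camera adjusted p was 0.00015 (adjusted p = 0.0383 with an estimated correlation). The Notch, TGF-beta, Hippo-YAP and retinoic acid lists did not pass camera. Of 10 Notch pathway genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone, adjusted p = 0.206), among them the ligands Jag1 (−0.52) and Jag2 (−0.54). Of 15 TGF-beta response genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone, adjusted p = 0.206), with Ltbp2 (−0.60) and Id2 (−0.42) lower and Tgfbr2 (0.37) and Tgfbi (0.21) higher, and 3 fell without KO replicates 2 and 3. Of 14 Hippo-YAP targets, 5 rose and 5 fell (5 and 5 adjusted over the list alone, adjusted p = 0.764). Ctgf (−0.84) and Cyr61 (−0.37), matricellular proteins induced by YAP, and the kinase gene Lats2 (−0.37) fell while Nt5e (0.84) rose, and the median (−1.74e-05) and mean (0.000714) of that list differed in sign, its test directed up. Of 13 retinoic acid genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone, adjusted p = 0.783), with the retinol importer Stra6 (−0.62) lower and Dhrs3 (0.69) and Rarg (0.32) higher. The median of that list was 0.071 and its mean −0.0012, its test directed up. Ltbp2, Ctgf, Lats2 and Stra6 overlap other genes.

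Of 15 matrix proteases and protease inhibitors tested, 10 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.30. Besides Mmp3 and Mmp13, Mmp10 went from 12.6 ± 1.22 to 31.9 ± 2.61 CPM (1.33, SE 0.0843), and Adamts12 fell (−0.71, SE 0.0602), where library totals alone gave 3 falls. Camera gave an adjusted p of 0.000192, and with an estimated correlation an adjusted p of 0.0722. The matrix itself went both ways: of 31 collagens and matrix genes, 9 rose and 10 fell (9 and 11 adjusted over the list alone, camera adjusted p = 0.509), and the 4 named members all fell, Postn (−1.61, SE 0.0986), Thbs2 (−1.59), Mgp (−1.41) and Fbln1 (−0.89). Of 15 transcription factors and mesenchymal genes of epithelial-mesenchymal transition, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0646). Fibronectin, Fn1, went from 5719 ± 338 to 8624 ± 405 CPM (0.59), N-cadherin, Cdh2 (0.46), and the hyaluronan receptor Cd44 (0.55) rose, and Mmp2 fell (−0.21). That list passed without EV replicate 4 (adjusted p = 0.0364), and its 7 rises became 4 without EV replicate 2, KO replicate 1 or KO replicate 4, with library totals alone and in FPKM (3 in FPKM without a filter). Of 12 smooth muscle genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.0646), among them Cnn1 (−0.87), Mylk (−0.37), Tagln (−0.29) and Smtn (−0.21). This list passed without EV replicate 4 (adjusted p = 0.0198) and without KO replicate 4 (adjusted p = 0.0351). Fn1, Cdh2, Mylk, Tagln and Smtn overlap genes on the opposite strand.

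Guidance genes, the semaphorins, ephrins, slits and their receptors, rose more often than they fell: of 29 tested, 13 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.13. Slit2 (0.61, SE 0.0487), Sema3c (0.46), the ephrin receptor Epha4 (0.89) and Nrp1 (0.30) rose. The camera adjusted p of 0.00675 was lost with an estimated correlation (adjusted p = 0.519), and 7 rose without KO replicates 2 and 3 or in FPKM. With 1 library left out, 9 to 14 rose and 1 or 2 fell. Of 11 cadherins, claudins and junction genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.176). Cldn15, a claudin of tight junctions, went from 18.8 ± 1.86 to 4.98 ± 0.708 CPM (−1.91, SE 0.113), Pkp2 (−0.33) fell and Cgn rose (0.29), and 3 fell without KO replicate 4. Over the fits without 1 library, rises ranged from 1 to 3 and falls from 3 to 5.

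Epicardial and mesothelial markers split. Of 22 tested, 5 rose and 8 fell (6 and 8 adjusted over the list alone), and camera gave an adjusted p of 0.517 with a median of −0.035 and a mean of 0.032, its test directed down. Krt8 and Krt18 (0.54, SE 0.0438), the keratins of simple epithelia, and mesothelin, Msln, at 0.44, rose, while the zinc finger gene Bnc2 fell (−0.95, SE 0.0850). Markers of other cell types were few. Of 4 cardiomyocyte genes tested, 0 rose and 1 fell (1 and 1 adjusted over the list alone): troponin Tnnt2 fell from 145 ± 4.70 to 115 ± 7.27 CPM, and Myh6 was at 0.968 ± 0.944 and 2.30 ± 0.710 CPM (adjusted p = 0.0611). Without EV replicate 4, 2 cardiomyocyte genes rose, and 2 fell without EV replicate 3 or any of the KO replicates. Of 6 endothelial genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.344), the angiopoietin receptor Tek (0.42), and the receptors Kdr (−0.58) and Robo4 (−1.44), which stood at 1.65 CPM in EV. The call of Tek was lost without EV replicate 2 or 3 or KO replicate 2 or 4, with library totals alone, in FPKM and without KO replicates 2 and 3. Of 3 macrophage genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone), Cd68 (0.73) and Cd14 (−0.28), the latter call lost without EV replicate 2 or 3 or KO replicate 1, 2 or 4. Of 6 neural genes, 2 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.998), Tubb3 (0.99), Nes (0.21), Ncam1 (−0.54) and Uchl1 (−0.52). The median of that list was −0.16 and its mean 0.00087, its test directed down. The median was 0.21 in DESeq2 (9 tested) and 0.39 without a filter (13 tested), and the test turned up with library totals alone and without EV replicate 1, 3 or 4 or KO replicate 3 or 4. No germ line gene had enough counts to be tested (0 of 17). Of 29 HOX and developmental regulators, 6 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.267), with Hoxb8 at 0.48 and Pbx3 at −0.57, and 2 rose without KO replicates 2 and 3.

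Of 19 genes of cholesterol synthesis and its regulation tested, 0 rose and 15 fell (0 and 16 adjusted over the list alone), with a median of −0.23. Among them were Insig1 (−0.61, SE 0.0516), which holds the sterol-sensing complex in the endoplasmic reticulum, the sterol carrier Stard4 (−0.55, SE 0.0528) and the synthesis enzyme Msmo1 (−0.52, SE 0.0612). The camera adjusted p of 4.45e-08 was lost with an estimated correlation (adjusted p = 0.0769). Without KO replicates 2 and 3, 9 fell. Of 16 lipid storage genes and PPAR targets, 2 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.404), with the lipid droplet protein Plin2 at 0.53 and Angptl4 at 1.15, and 4 fell with library totals alone. Leaving out 1 library gave 2 or 3 rises and 1 to 3 falls.

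Ribosomal protein transcripts were slightly higher in KO. Of 30 tested, 28 rose and 0 fell (30 and 0 adjusted over the list alone), with a median of 0.25, among them Rps19 (0.44, SE 0.0804), Rpl23 (0.42), Rps18 (0.31) and Rpl5 (0.22). The camera adjusted p of 8.73e-08 was lost with an estimated correlation (adjusted p = 0.519). The number that rose was 9 in FPKM with either pseudocount, 2 in FPKM without a filter and 18 without KO replicates 2 and 3, and reads of these genes may be shared with their pseudogenes. Of 12 mitochondrially encoded genes, 5 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 0.28. The transcripts mt-Nd6 (0.48), mt-Nd4 (0.37), mt-Cytb (0.33) and mt-Co1 (0.30) rose. Here too the camera adjusted p of 0.00675 was lost with an estimated correlation (adjusted p = 0.519), and 3 rose without EV replicate 2 or KO replicate 4 and in DESeq2. Mitochondrial genes held between 0.488 and 0.768% of the counts of a library. Of 26 nuclear genes of oxidative phosphorylation, 4 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.320), with Ndufa1 at 0.77 and Ndufa4 at −0.30. The number that rose was 9 without EV replicate 1 and 2 without EV replicate 3, KO replicate 1 or KO replicate 3 or with library totals alone, and 1 in FPKM.

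The lists of hypoxia and glycolysis, NRF2 targets, the unfolded protein response, heat shock and the clock did not pass camera. Of 19 genes of hypoxia and glycolysis, 3 rose and 4 fell (4 and 5 adjusted over the list alone, adjusted p = 0.959), with Hk2 (0.38) and Pdk1 (0.30) higher and the oxygen sensor Egln3 (−0.68) and the reference gene Gapdh (−0.20, 1612 ± 66.6 to 1406 ± 81.6 CPM) lower. The median of that list was 0.017 and its mean −0.0075, its median was −0.034 with library totals alone, and 2 fell without EV replicate 3, KO replicate 1 or KO replicate 4. Of 13 NRF2 targets, 2 rose and 2 fell (3 and 3 adjusted over the list alone, adjusted p = 0.517), with Osgin1 at 0.63 and Me1 at −0.37. Of 20 genes of the unfolded protein response and ATF4, 7 rose and 2 fell (7 and 3 adjusted over the list alone, adjusted p = 0.125), among them Sdf2l1 (0.48), Ddit3 (0.33), Ero1l (0.20) and Psat1 (−0.22). The 7 rises became 4 without KO replicate 4 (also with library totals alone) and 2 in FPKM. Of 9 heat shock genes, 2 rose and 3 fell, over all genes and adjusted over the list alone (adjusted p = 0.959), among them Dnaja1 (0.19), Hspe1 (0.19), Hspb1 (−0.50) and Hsph1 (−0.21), and the call of Hspe1 was lost without EV replicate 3 or KO replicate 1 and 0 rose in FPKM. Of 17 clock genes, 1 rose and 6 fell, over all genes and adjusted over the list alone (adjusted p = 0.397), Npas2 (0.63) against Hlf (−1.34), Cry1 (−0.28) and Bhlhe40 (−0.20) among others, and 2 fell without KO replicates 2 and 3.

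The lists of interferon-stimulated genes, MHC class I and NF-kB targets did not pass camera either. Of 18 interferon-stimulated genes, 5 rose and 1 fell (6 and 3 adjusted over the list alone, adjusted p = 0.267), with Bst2 (0.42), Irf9 (0.44), Ifi27 (0.31) and Ifit1 (from 1.27 to 2.56 CPM) higher, and 3 rose without KO replicates 2 and 3, where the median turned from 0.23 to −0.029. The number that fell was 0 without EV replicate 4 or KO replicate 4, 2 without EV replicate 1 and 3 with library totals alone. Of 10 genes of MHC class I presentation, 2 rose and 0 fell, over all genes and adjusted over the list alone (adjusted p = 0.279), Psmb10 (0.34) and H2-D1 (0.22). Of 14 inflammatory cytokines and NF-kB targets, 1 rose and 4 fell, over all genes and adjusted over the list alone (adjusted p = 0.517). The adhesion molecule Icam1 (−1.16), the acute-phase gene Saa3 (−0.88) and the chemokines Ccl7 (−0.47) and Ccl2 (−0.37) fell. The median of that list was 0.0075 (−0.044 with library totals alone), its mean −0.11 and its test directed down.

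Of the complex that holds Hdac3, 6 genes were tested, and 3 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.508). Among them Tbl1x (0.22) and Tbl1xr1 (0.20) rose, and Ncor1 was at −0.11 (SE 0.0607, adjusted p = 0.209). The number that rose was 1 without EV replicate 2 or 3, KO replicate 1 or KO replicate 2, with library totals alone and in FPKM. Of 12 other histone deacetylases, 3 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.397), among them Hdac7 (0.27) and Hdac6 (0.23). Of 12 nuclear receptors that bind the complex, 3 rose and 5 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.546), with the thyroid hormone receptor Thra (0.37) higher and the vitamin D receptor Vdr (−0.69), the glucocorticoid receptor Nr3c1 (−0.25) and Nr2f2 (−0.34) lower.

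MicroRNAs themselves were not measured in these libraries, so the lists bear on their host transcripts and targets. C430049B03Rik (chromosome X, 53055046 to 53057190), a noncoding transcript, rose from 56.2 ± 2.78 to 77.8 ± 4.18 CPM (0.47, SE 0.0554, edgeR adjusted p = 3.36e-06). GENCODE M21 places the hairpins of miR-322 and miR-503 on the same strand, 696 and 991 bases beyond its end. Of 13 microRNA host transcripts, 4 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.739), with Rian (0.65) higher and Mest (−1.15) and H19 (−0.70) lower. Of 25 genes listed as targets of miR-15, miR-16, miR-322 and miR-503, 2 rose and 13 fell (2 and 14 adjusted over the list alone), with a median of −0.26. Fgf9, Igf2 and Kif23 fell and Ccnd1 rose. The camera adjusted p was 2.02e-05 (adjusted p = 0.0383 with an estimated correlation). The list shares genes with those of growth factors, DNA replication and D cyclins and includes the pair named from published work, so its direction is not independent evidence. Without Fgf9 and Igf2, 2 of 23 rose and 11 fell, with a camera adjusted p of 0.00065 and an adjusted p of 0.0769 with an estimated correlation. Of 13 genes of the microRNA machinery, 2 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.959), with Dgcr8 at 0.21 and Ago2 at 0.20, where the call of Ago2 was lost without EV replicate 1 or 2 or KO replicate 2 and that of Dgcr8 without KO replicate 4, and 0 rose with library totals alone or in FPKM. The number that fell ranged from 0 to 2 with 1 library left out. Of 19 imprinted genes, 5 rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.279), with Igf2, Mest, H19 and Grb10 (−0.63) lower, and the 5 rises became 3 without EV replicate 1 or KO replicate 4 or with library totals alone, and 2 in FPKM.

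**Figure D3:**
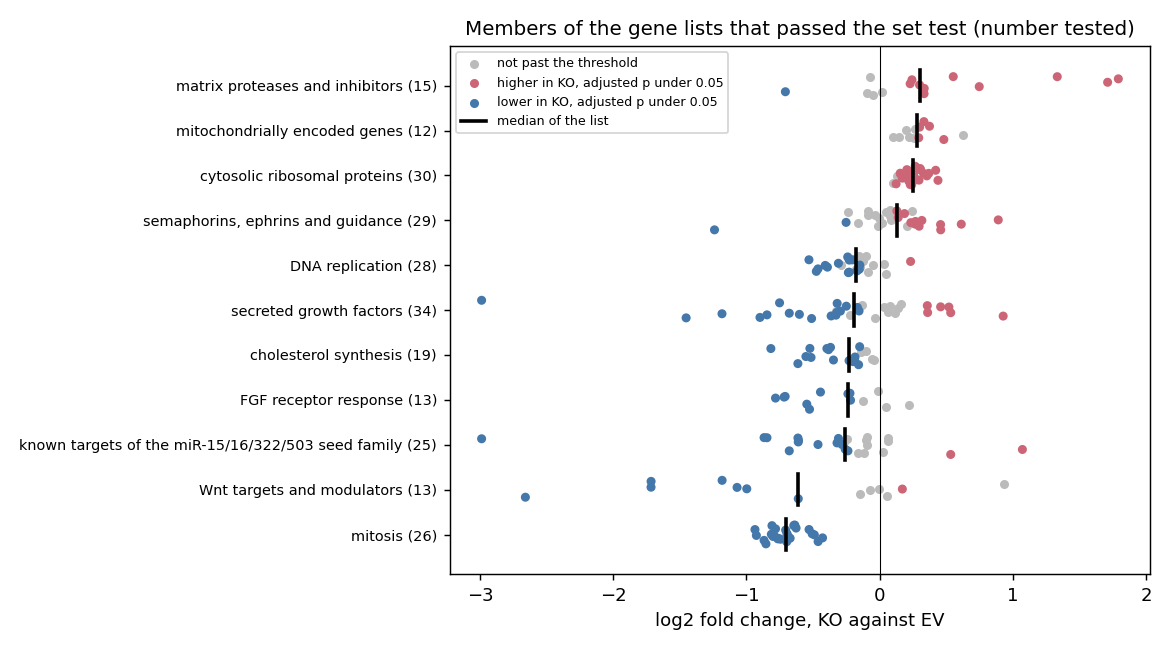
Log2 fold change, KO against EV (horizontal axis), of each tested member of the 11 gene lists that passed camera; each point is a gene, colored when its adjusted p in edgeR was under 0.05, and black bars are list medians. The median runs from −0.70 for mitosis to 0.30 for matrix proteases and inhibitors, and all 26 genes of mitosis lie below 0.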

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

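The tests of KO replicate 1's label, of the liver genes and of the ribosomal protein genes were chosen only after the results they measure were seen.

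In 20 of 338 groups of 4 libraries (5.92%), the highest or lowest library stood apart from the others by more than Dixon's 95% critical ratio allows, and chance gives about 1 in 20. In EV, the CPM of Flt4 was 12.7 in replicate 2 against 14.8 or more in the others, and that of Sema6a was 13.0 in replicate 1 against at most 11 in the others. Etv5 stood at 40.1 CPM in EV replicate 4 against 43.6 to 44.2, Mylk at 772 CPM in EV replicate 4 against 661 to 679, and Smtn at 182 CPM in EV replicate 1 against 167 to 169. Flt1 was at 14.3 CPM in EV replicate 3 against 15.8 to 16.1, Saa3 at 149 CPM in EV replicate 2 against 88.8 to 97.8, and Osgin1 at 12.5 CPM in EV replicate 2 against 10.4 to 10.6. Rps19 was at 247 CPM in EV replicate 4 against 333 to 349, and Grb10 at 986 CPM in EV replicate 4 against 896 to 902. Egln3 stood apart in both groups, at 35.7 CPM in EV replicate 2 against 33.0 to 33.4 and at 20.3 CPM in KO replicate 4 against 21.3 to 21.4. In KO, Lamc3 was at 2.28 CPM in replicate 1 against 1.55 to 1.67, Plk2 at 81.9 CPM in replicate 4 against 73.2 to 74.4, and Icam1 at 2.08 CPM in replicate 4 against 2.69 to 2.76. Id2 was at 18.6 CPM in KO replicate 2 against 24.4 to 24.9, Jag2 at 4.35 CPM in KO replicate 3 against 3.34 to 3.49, Gapdh at 1280 CPM in KO replicate 2 against 1440 to 1460, and Cgn at 108 CPM in KO replicate 2 against 92.8 to 95.1. The share of counts in the 10 most abundant genes was 7.99% in KO replicate 4 against 7.70 to 7.72%.

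The Hdac3 transcript did not differ detectably between the groups, and the characteristics of KO replicate 1 name the empty vector. Of 2600 genes past the threshold in the other 7 libraries, KO replicate 1 lay closer to the KO mean for 93.3%, where the other KO libraries gave 82.8 to 90.9% and the EV libraries 9.96 to 25.9%, which argues against its being an empty-vector library. The edit itself, the change in Hdac3 protein and the effect of Hdac3 loss on other genes were not tested here. They stay open as the biological difference that the design names.

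Of 47 liver genes listed, 15 had enough counts to be tested, of which 8 rose and 1 fell in KO, and 40 of the 44 detected had a higher mean in KO, though of the 3 with an EV mean of at least 1 CPM only Alb was higher. After each group was centred, Alb followed the sum of the other liver genes over the 8 libraries (Pearson r = 0.987, permutation p = 0.0052; Spearman rho = 0.976, permutation p = 0.0208; r = 0.988 without the 2 libraries farthest from the median), and RNA or reads from liver in the libraries may account for this. From EV to KO, total counts went from 5 to 77 for Apoa1, 20 to 117 for Cyp2e1 and 2 to 50 for Mup3, while Apoc3 (13 and 13), Fgb (21 and 22), Hp (567 and 381) and Hpx (98 and 65) did not follow. A rise of these genes in the KO cells that varies between replicates was not tested and stays open, and most of their counts are near the floor.

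Ribosomal protein genes were higher in KO, with a median log2 fold change of 0.25. Of 10000 lists matched on gene length and expression, 100% had a lower median (typically 0.12), so the shift of matched genes did not reach that of this list. The matched genes were drawn singly and need not vary together as these do, and the closeness of the match was not measured. The test therefore cannot exclude a trend with length and expression as the whole cause. Fold changes did fall with length over all genes (Spearman rho −0.16 across genes, which are not independent replicates). The list's mean log2 CPM was 9.09 to 9.43 in EV and 9.46 to 9.59 in KO, a difference of group means of 0.257 that exceeds the SD within EV (0.141) and within KO (0.0618), and every KO library lay above every EV library (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allow). A demand for such a separation is too weak to exclude a chance co-variation of these genes between libraries, since chance gives it for 2.86% of lists and this one was picked after 42 lists had been tested. Its members vary together (estimated correlation 0.655), and the list did not pass with that correlation (camera adjusted p = 0.519). Chance co-variation and a difference between the EV and KO cells therefore cannot be told apart. That reading was adopted, with a stricter demand on the gap between the groups (0.029), after the result was seen.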

How the results depend on the processing

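The fits without KO replicates 2 and 3 and the list tests without Fgf9 and Igf2 were chosen only after the result was seen. The count of 3324 genes stayed between 2575 and 3737 in all alternatives set beforehand (2621 without KO replicate 1 to 3359 without EV replicate 1 where 1 library was left out). A similar count does not mean the same genes. Of the 3324, 3111 also passed in DESeq2, 2750 with library totals alone and 2552 without KO replicate 1. In FPKM with a pseudocount of 1, 2447 of them passed, or 2197 without a filter. No gene that passed both in the main test and in another setting had opposite signs. Without KO replicates 2 and 3 the count of genes was 1974 (880 higher, 1094 lower), 1902 of them shared with the main test, with fewer libraries. The count of genes higher in KO was 1039 with library totals alone, 896 and 897 in FPKM with a pseudocount of 1 and 0.1, and 766 in FPKM without a filter. These settings do not correct for library composition and move the median log2 fold change of all genes from 0.005 to −0.046 (library totals).

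The log2 fold change of Hdac3, KO against EV, turned sign without EV replicate 3 (0.0116), without KO replicate 2 (0.0320) and without KO replicates 2 and 3 (0.0244). With 1 library left out it ranged from −0.0226 to 0.0320, and its adjusted p from 0.424 to 0.973 over all its alternatives never passed. The values without a correction for composition lay farthest from 0, at −0.0561 with library totals alone and −0.0539 to −0.0568 in FPKM, beyond the standard error of the main test (0.0528). Of the 42 gene lists tested, 11 passed in the main test, 10 without Fgf9 and Igf2, and 10 to 13 with 1 library left out. With an estimated correlation 5 passed, and the cause of the losses was not tested. The secreted growth factors were lost (adjusted p = 0.102 in camera) although their estimated correlation, −0.0116, lay below the preset 0.01. A correlation between its members therefore does not account for the loss of that list. The other lists lost had estimated correlations from 0.0311 (matrix proteases and inhibitors) to 0.655 (cytosolic ribosomal proteins). With fry, which does not compare a list with other genes, 23 passed, without the mitochondrially encoded genes (adjusted p = 0.0513). For the other 164 named genes, 3181 of 3274 values kept their direction and side of the threshold, 87 no longer passed, 6 passed newly and 0 reversed. Apart from Fgf9 and Igf2, these genes were named by their fold change or adjusted p in the main test. Their stability was thus partly set by that choice and does not carry over to other genes. With the replicate number as a block 3737 genes passed. The labels do not say that numbers pair the samples, and after group means were removed the correlation of libraries that share a number was 0.124, −0.034, 0.063 and 0.091, while 6 of the 8 libraries correlated best with the library of the other group that has their own number, so a pairing by number is not excluded. A count of 3 equals 0.122 to 0.166 CPM, so smaller levels were not detectable at this depth.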

Other observations

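The genes, families, neighbours of C430049B03Rik and chromosome windows named in this part, and their tests, were chosen only after the result was seen, and the test of seed sites was chosen after the median of the target list had been seen but before its own result. Several growth factors beyond those named above differed in KO. Angpt1, a ligand of the receptor Tek, went from 4.78 to 1.73 CPM (log2 fold change −1.45), Fgf2 from 14.5 to 9.05 CPM (−0.68) and Fgf1 from 4.57 to 2.72 CPM (−0.75), while Fgf5 went from 7.80 to 14.8 CPM (0.93) and Vegfa from 51.1 to 74.0 CPM (0.53). Of imprinted genes in the Dlk1 and Meg3 region, Dlk1 went from 82.7 to 48.0 CPM (−0.78), Meg3 from 8.42 to 12.9 CPM (0.61) and Rian from 64.2 to 101 CPM (0.65).

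On chromosome X, the noncoding transcript C430049B03Rik (0.47) is followed by the hairpins of miR-322 and miR-503. Plac1, 12805 bases away, rose by 1.78 on the log2 scale (SE 0.0684, edgeR adjusted p = 8.99e-13), and Gpc3, a glypican gene 441096 bases away, fell from 1118 to 565 CPM (−0.99, SE 0.0510). Between and around them Hprt was at 0.17 (adjusted p = 0.0244), Phf6 at −0.0026 (adjusted p = 0.978) and Gpc4 at −0.055 (adjusted p = 0.551), so neighbours in this region went different ways.

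Of 389 families formed by symbol stem, keratins (7 of 11 rose, 2 fell, camera adjusted p = 0.0153), Serpinb genes (5 of 6 rose, 1 fell, adjusted p = 0.0120), Serpina genes (4 of 6 rose, adjusted p = 0.0120), matrix metalloproteinases (10 of 14 rose, 2 fell, adjusted p = 0.0236) and Tnfrsf receptors (6 of 12 rose, 1 fell, adjusted p = 0.0484) held more rises than falls. Kinesins (14 of 31 fell, 1 rose, adjusted p = 0.00138), Mcm genes (7 of 10 fell, adjusted p = 0.0161), Cdca genes (5 of 7 fell, adjusted p = 0.00262) and Wnt ligands (4 of 6 fell, 1 rose, adjusted p = 0.0480) held more falls. None passed with an estimated correlation (adjusted p = 0.920 for each), and no median of these families changed sign with library totals alone. The estimated correlation of the Serpinb genes, −0.00033, lay below the preset 0.01, so a correlation between members does not account for that loss. The other families named here had 0.0158 (Tnfrsf) to 0.308 (Wnt).

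Of the 35 splits of the 8 libraries into 4 and 4, only the real split itself reached 3324 genes (highest other 0 in edgeR). Every other split mixes EV and KO libraries, so a group difference widens the spread within its parts and lowers its count. The 0 calls elsewhere are thus no separate evidence. A share of 1 in 35 is the smallest that these splits can give, so chance is not excluded by this count. For gene lists, too, only the real split gave as many as 11. The highest other gave 10, in splits that exchange a single EV and KO library and so keep most of the real grouping. Splits whose parts hold EV and KO libraries in equal numbers gave between 0 and 4 lists, with 0 genes called. The 4 came with EV replicates 1 and 3 beside KO replicates 1 and 4. Camera with the preset correlation thus passed some lists where the groups were balanced.

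A hypothesis was that more activity of the seed family of miR-15, miR-16 and miR-322 in KO lowers genes with its site. The site TGCTGCT lay in the 3' UTR of 3005 of 11783 genes, with a coefficient of −0.017 (SE 0.0082) on the log2 scale, rank 36 from the lowest among the 210 orderings of its bases. The miR-503 site CGCTGCT lay in 581 genes, with a coefficient of −0.013 (SE 0.015), rank 60 of 210. Neither rank lies among the lowest 5% that had been asked for, which the rule written before the result counted against the hypothesis. Other orderings of the same bases reached coefficients of −0.116 for the first site and −0.157 for the second. In size, the coefficient of the first site exceeded its standard error and that of the second did not, with genes taken as independent. A small effect is thus not excluded for either site, a reading that the rule did not include. Fgf9 has 1 TGCTGCT site and Igf2 has 2, and the median of the target list had been seen before this test was written down.

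Over windows of 30 genes, the largest median was −0.23, on chromosome 6 from 52546228 to 58692869 (1229 windows, permutation p = 0.004 over 1000 shuffles of gene order, where the shuffled 95th percentile was 0.194). The shuffles treat neighbouring genes as exchangeable and do not use the spread between libraries. That p therefore does not judge a difference between EV and KO in this window.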
